A study of Caenorhabditis elegans with 2 samples.

How the data were processed

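Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out, per the labels, on whole Caenorhabditis elegans at the L3 larval stage, males and females pooled. The strain carries an integrated transgene with a GFP-tagged copy of nhr-11, a gene of the nuclear hormone receptor family. It is mutated in unc-119, and the transgene also carries an unc-119 rescue. The antibody label names nhr-11 and the description names the tagged protein, so the epitope is not settled. The labels describe 2 biological replicates of 1 group and a fragment size range of 150 to 350 bp. No second condition was given, so no comparison between groups was made, and all tests compare positions in the genome.

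The deposited files used here were 8 peak lists, 4 on the ce10 build and 4 on the ce11 build of the worm genome. Per the file headers and accompanying descriptions, each build had a candidate list for replicate 1, one for replicate 2, one from both replicates pooled, and a reproducible list kept after an irreproducible discovery rate (IDR) threshold, a filter based on how ranks match between replicates. Each candidate list held 30000 regions and was meant to include background as input for that filter. The peak signal value of each region was assigned by the authors' caller from the sample alignment and a control alignment, per the deposited descriptions, and its scale was not stated. The deposited score beside it fell below 0 in the candidate lists, to -0.231 in the pooled ce11 list, and was used only to describe the files. The caller, the aligner and their versions were not given in the sources used here. The control library was not analysed here. The lists hold no read counts, so the sequencing depth of each sample is unknown, and no interval for single peak signals can be given. Signal values were used to rank regions within a list and not to compare levels between lists.

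The reproducible ce11 list was compared with the pooled list, and its 1030 regions were the 1030 strongest pooled regions by signal. On ce10 the same held for 1024 of 1024 regions. The IDR step therefore set the number of regions kept, and a single listed region need not be among the strongest in each replicate alone. Calling with a fixed region width, 356 bases for 1026 of the 1030 regions, also means that region width carries no information on the extent of binding.

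Positions on ce11 were joined to the WBcel235 annotation of Ensembl release 115, which is the same build, and coordinates are given 1-based on ce11. Analyses of the ce10 lists used no annotation, but expectations from chromosome length used the lengths of WBcel235 for both builds. A gene was called bound when a reproducible peak summit lay from 1000 bases upstream to 500 bases downstream of its annotated 5′ end, and 19973 protein-coding genes were considered. Genes were matched to lists by symbol, and 97 symbols were shared by more than 1 gene record. A summit was assigned to 1 feature class in the order 5′ UTR, coding sequence, 3′ UTR, exon of a noncoding gene or pseudogene, intron, and intergenic; this classification was added after the data were examined.

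Peak positions were compared with 10000 random placements that kept the number of peaks per chromosome, or that followed chromosome length or gene number, in permutation tests. The 23 gene lists were tested with Fisher's exact test against all other protein-coding genes. The 12 fixed sequence words were counted within 50 bases of each summit and compared with windows centred 300 bases away with an exact McNemar test on 1 flank drawn at random, and all 2080 words of 6 bases were ranked the same way. Noncoding genes of 5 classes were searched within 250 bases of summits. Tests were two-sided except that of replicate overlap, p-values were adjusted by the Benjamini-Hochberg method within each family with a threshold of 0.05, and shares carry 95% Wilson intervals, which cover counting error only. Neighbouring genes share promoters and lie in clusters, so genes and peaks are not independent replicates. The smallest p these permutations can give is 0.0001.

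The groups, tests, gene lists, sequence words and the following rule were fixed before the data were examined. Named items were the 20 strongest reproducible peaks with each protein-coding gene in whose window the summit lay, or the nearest such gene where there was none; nhr-11 and unc-119; up to 4 bound members with the strongest peaks of each list past the threshold; and up to 4 bound members of the intestine, heterochronic and nuclear hormone receptor lists. Alternatives covered the window, the assignment of peaks to genes, the flank, the distance, the overlap, the number of regions, the build, the 515 strongest peaks, each replicate alone, and a Cochran-Mantel-Haenszel test within 5 strata of the distance to the upstream gene. Restriction to peaks among the strongest regions of both replicates, and to peaks with at least 90% of their 31-base words found once in the genome, were chosen after seeing the data. The latter peaks were compared with placements in the 83.7% of positions where a region of 356 bases passes the same limit, and with the 19552 genes that have such a position in their window.

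The statistics were tested on simulated data. A planted list with 40 bound members was called, and 0 of 40 random lists were. With all peaks placed at random, 4 of 100 placements gave any list call over the 23 lists. These placements were uniform along the genome, so this rate need not hold for peaks that favour gene starts. A word planted at random summits, and found in 20.1% of 1030 windows, was called, and 0 of the 11 other words were. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.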

Results

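Binding of NHR-11, a nuclear hormone receptor, was profiled by ChIP-seq in whole L3 larvae of a C. elegans strain with a GFP-tagged copy, with 2 biological replicates. Whether the antibody recognised the tag or the receptor itself is not settled by the labels. The reproducible ce11 list held 1030 peaks that covered 364 kb, with peak signal values, as given by the authors, from 54.9 to 899 and a median of 73.8. On ce10 the list held 1024 peaks, and at matched ranks the signal values of both builds had a median ratio of 1.00 and a range of 0.983 to 1.02. Read depth is unknown, since the lists hold no counts.

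The strongest regions of both replicates overlapped more often than by chance. Of the 1030 strongest regions of replicate 1, 657 (63.8%) overlapped one of the 1030 strongest of replicate 2 by at least 1 base, against 0.764% with random placement (one-sided permutation test, p = 0.0001, the smallest possible). Among the 657 shared regions the signal values had a Spearman correlation of 0.672 across regions, which are not independent replicates and were selected as strong in both, and over the 1027 reproducible peaks listed in both replicates the correlation was 0.502. Of the 1030 reproducible peaks, 652 (63.3%) lay among the 1030 strongest regions of both replicates, 346 of 1 replicate and 32 of neither. With the list cut into 5 equal parts by signal, the share in both fell from 100% in the strongest part to 7.28% in the weakest.

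**Figure D1:**
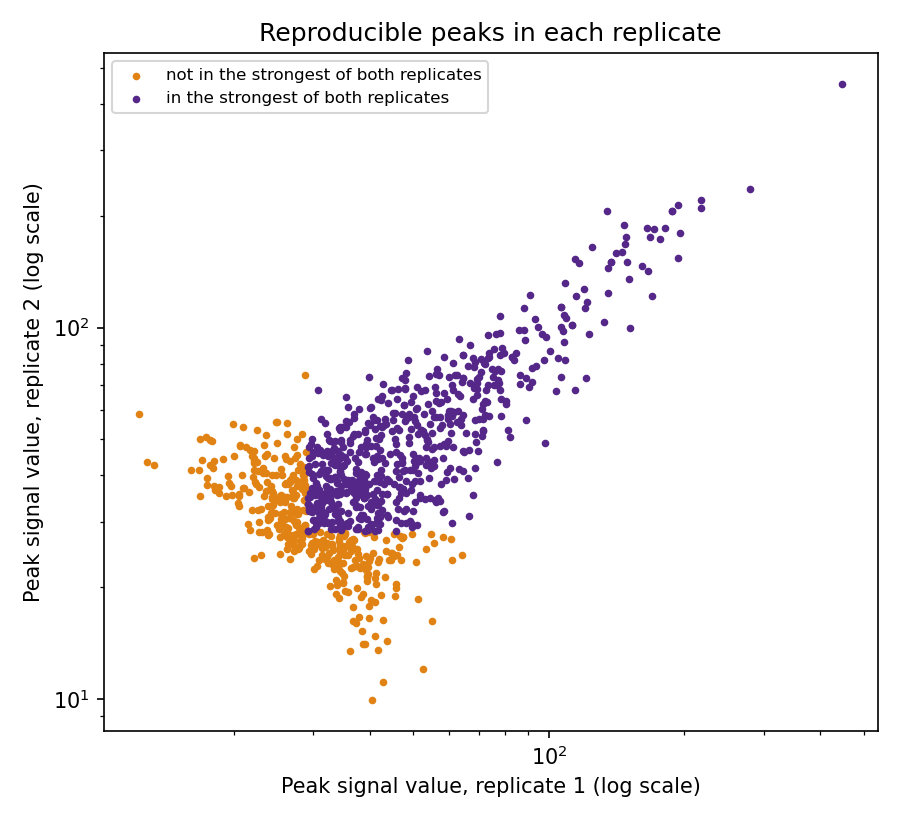
Peak signal value of each reproducible peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales and without units; each point is 1 peak listed in both replicates (1027 peaks), coloured by whether it lay among the 1030 strongest regions of both. The 652 peaks that did occupy the upper right of the plot, as this definition requires.

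The strongest peak lay upstream of cdc-48.1 (WBGene00007352), which encodes an AAA ATPase of protein quality control. It spanned II 10563462 to 10563684, with an intergenic summit 171 bases upstream of the gene start and a signal of 899, and it ranked first in both replicates. The second, at III 3867477 to 3867651, lay 282 bases upstream of rpl-3 (WBGene00004414), a protein of the large ribosomal subunit, with a signal of 516. The third, at III 10759074 to 10759429 with a signal of 433, lay between the divergent genes tasp-1 and K01G5.10. Further intergenic summits among the 20 strongest peaks were 63 bases upstream of iff-2, a translation factor shared in its window with F54C9.14, 111 bases upstream of the histone gene his-37, and 394 bases upstream of hsp-1, which encodes a constitutive heat shock protein of the HSP70 family. The set held further ribosomal protein genes, namely rpl-35 with a signal of 345, rpl-20 with 306, shared with Y17G9B.5, and rpl-15 with 305, shared with K11H12.8. The rpl-20 peak was nearer to the start of Y17G9B.5.

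Of the 20 strongest peaks, 7 on X and 4 on autosomes lay outside every gene start window. The strongest of these, at X 13700689 to 13701044 with a signal of 426, was intergenic and 6040 bases from the start of K02D3.1. The peak at X 8036311 to 8036410, with a signal of 394, was intergenic and 4938 bases upstream of xol-1, the switch gene of sex determination and dosage compensation. The other 5 on X had signals from 313 to 373 and were nearest to cest-16, W02H3.3, C30E1.4, F19H6.5 and ZK899.6, and the one nearest to cest-16 had its summit in an intron. On autosomes the peak nearest to F43C1.7 (III, signal 410) was intergenic. The one nearest to the calmodulin gene cmd-1 (V, signal 354) lay in an exon of the noncoding gene linc-128. Those nearest to nhr-19 (II, signal 341) and mnk-1 (II, signal 312) lay in introns.

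Genes of protein synthesis carried peaks far more often than other genes. The other genes were not matched for expression level, and whether the peaks are particular to NHR-11 was not tested. A peak summit lay at the start of 44 of 83 cytosolic ribosomal protein genes (53.0%, interval 42.4 to 63.4), from 41 distinct peaks, against 3.09% of other protein-coding genes (odds ratio 35.4, Fisher's exact test, adjusted p = 7.9e-42). With each peak given to its nearest gene only, 24 of these 83 genes were bound (28.9%, odds ratio 16.4, exact test, adjusted p = 6.9e-18). Translation factor genes were bound in 8 of 39 cases (20.5%, odds ratio 7.64, exact test, adjusted p = 0.000154), with iff-2, eef-1G, eef-1A.1 and eef-2 the strongest at signals of 372, 153, 136 and 120, and with windows of 2000 bases to each side the odds ratio was 4.72 (exact test, adjusted p = 0.00297). Heat shock and chaperonin genes were bound in 8 of 34 cases (23.5%, odds ratio 9.12, exact test, adjusted p = 7.5e-05), led by hsp-1 at 314, cct-1 at 169, hsp-110 at 167 and cct-7 at 142, and with the nearest gene only 4 of 34 were bound (odds ratio 5.18, exact test, adjusted p = 0.0391), and with the 515 strongest peaks the odds ratio was 17.1 (exact test, adjusted p = 1.5e-06). Oxidative phosphorylation genes were bound in 7 of 62 cases (11.3%, odds ratio 3.76, exact test, adjusted p = 0.0161), led by cox-5A at 191, cox-5B at 178, atp-1 at 118.9 and ndua-8 at 71.6. The call for oxidative phosphorylation was lost with the 515 strongest peaks (odds ratio 2.78, exact test, adjusted p = 0.234), with peaks among the strongest of both replicates (odds ratio 3.18, exact test, adjusted p = 0.143) and in peaks of unique sequence (odds ratio 3.30, exact test, adjusted p = 0.0517). This list was matched by symbols fixed beforehand and leaves out some subunit genes with other symbols, bound genes among them, so its count and order hold for the matched symbols only. The same limit applies to the heat shock and chaperonin list, which holds only some of the dnj genes and leaves out bound ones. The ndua-8 peak ranked 1481 in replicate 2 alone. Several of the peaks named here also lay in the window of a neighbouring gene. Those of cct-1, hsp-110, cct-7, eef-1A.1 and ndua-8 were nearer to the starts of mig-5, rpn-3, T10B5.4, rfc-4 and rbc-2, respectively. Those of eef-1G, eef-2 and atp-1 were shared with ctf-4, clsp-1 and mcrs-1.

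**Figure D2:**
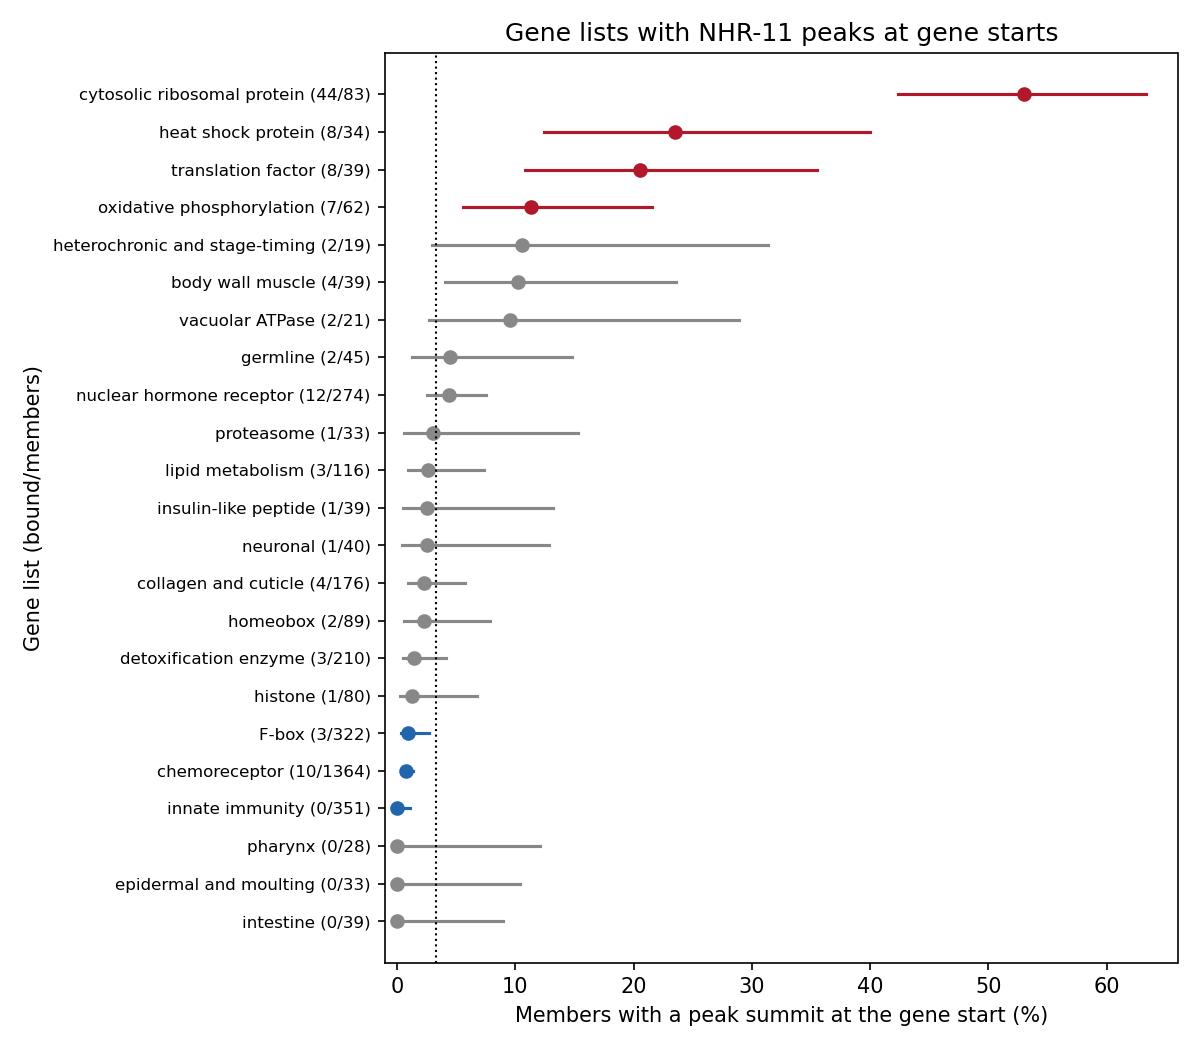
Share of each fixed gene list with a reproducible peak summit at the gene start (x axis, percent; points) with 95% Wilson intervals (lines); red lists were bound more often and blue lists less often than other genes past the threshold, and the dotted line marks the 3.30% of all protein-coding genes. Cytosolic ribosomal protein genes stand at 53.0%.

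The innate immunity, chemoreceptor and F-box lists were bound less often, again without matching for expression level. None of the 351 innate immunity genes matched by symbol had a peak (0%, Wilson interval up to 1.08%; exact test, adjusted p = 7.5e-05), and without replicate 2 there were 2 (odds ratio 0.178, Wilson interval up to 2.05%; exact test, adjusted p = 0.00976). The symbols do not cover every gene of immunity, so this holds for the matched genes only. Chemoreceptor genes were bound in 10 of 1364 cases (0.733%, odds ratio 0.204, exact test, adjusted p = 1.8e-09), the strongest being sri-5 at 100.1 and srw-145 at 82.2, and the odds ratio was 0.308 without replicate 1 and 0.153 without replicate 2 (exact tests, adjusted p of 3.0e-06 and 1.9e-10). F-box genes were bound in 3 of 322 cases (0.932%, odds ratio 0.272, exact test, adjusted p = 0.0360), namely fbxb-85 at 84.97, fbxa-84 at 55.9 and fbxb-72 at 55.3. The F-box call was lost in 6 alternatives, with adjusted exact or Cochran-Mantel-Haenszel p from 0.0589 to 0.275 at odds ratios from 0.167 to 0.378, and fbxa-84 was not among the 1030 strongest regions of either replicate. The sri-5 and fbxb-85 peaks also lay in the windows of rsr-1 and hex-3.

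The remaining 16 lists did not pass the threshold. Nuclear hormone receptor genes were bound in 12 of 274 cases (4.38%, exact test, adjusted p = 0.583), with nhr-48 at 118, nhr-10 at 105, nhr-138 at 87.4 and nhr-1 at 85.5. The nhr-138 peak was nearer to the start of C28D4.18. Heterochronic genes were bound in 2 of 19 cases (10.5%, exact test, adjusted p = 0.329), namely ain-1, a component of the microRNA silencing complex, at 171, and lin-66 at 82.4. Windows of 2000 bases to each side moved that list past the threshold (odds ratio 8.43, exact test, adjusted p = 0.00138). Body wall muscle genes were bound in 4 of 39 cases (10.3%, odds ratio 3.36, exact test, adjusted p = 0.112), and also passed with those wider windows (odds ratio 3.99, exact test, adjusted p = 0.00935), but 2 of 39 were bound without replicate 2 (odds ratio 1.71, exact test, adjusted p = 0.618) and with peaks among the strongest of both replicates (odds ratio 2.48, exact test, adjusted p = 0.466). No gene was bound of 39 intestine, 33 epidermal and moulting, and 28 pharynx genes, for which Wilson intervals reached 8.97%, 10.4% and 12.1%. Bound members numbered 4 of 176 collagen and cuticle genes, 2 of 89 homeobox genes, 1 of 40 neuronal genes, 2 of 45 germline genes, 3 of 116 lipid metabolism genes and 3 of 210 detoxification genes. They numbered 1 of 80 histone genes, 1 of 39 insulin-like peptide genes, 2 of 21 vacuolar ATPase genes and 1 of 33 proteasome genes. Without replicate 2, 1 of 176 collagen and cuticle genes was bound (odds ratio 0.179 in place of 0.680). In that setting 1 of 89 homeobox genes was bound (odds ratio 0.357 in place of 0.673). The vacuolar ATPase list passed without replicate 1 (odds ratio 7.37, exact test, adjusted p = 0.0104), and the lipid metabolism list with the wider windows (odds ratio 2.11, exact test, adjusted p = 0.0458).

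Peaks concentrated at gene starts and avoided coding sequence. Of the 1030 summits, 511 (49.6%, interval 46.6 to 52.7) lay in a protein-coding gene start window, against 26.0% ± 1.37 (SD over random placements), a ratio of 1.91 (permutation test, p = 0.0001), and 659 of 19973 genes (3.30%) were bound. By annotation, 631 summits (61.3%) were intergenic, compared with 34.7% of the genome, and 239 (23.2%) were in introns of protein-coding genes, compared with 32.8%. Exons of noncoding genes or pseudogenes held 96 summits (9.32%), compared with 3.14% of the genome. Coding sequence held 20 summits (1.94%) but 24.3% of the genome. These feature shares were compared without a test. The 519 summits outside the windows had a median distance of 2667 bases to the nearest gene start.

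Chromosome II carried the most peaks per megabase, 13.2, and chromosome V the fewest, 6.88, but with the 515 strongest peaks X (6.72) and III (6.24) stood above II (6.09). Relative to length, peaks on V were at 0.670 and those on IV at 0.739 of the expected number (permutation test, adjusted p = 0.0003 for each), and those on II were at 1.28 (permutation test, adjusted p = 0.001) and on III at 1.19 (permutation test, adjusted p = 0.0232). X carried 210 peaks, 1.15 times the number expected from its length (permutation test, adjusted p = 0.0328) and 1.49 times that expected from its number of genes (permutation test, adjusted p = 0.0003). The length-based call for X was lost without replicate 1 (ratio 1.11, permutation test, adjusted p = 0.129) and in peaks of unique sequence against placements in such sequence (ratio 1.03, permutation test, adjusted p = 0.651). In that setting I passed, at a ratio of 1.18 (permutation test, adjusted p = 0.0316), in place of 1.12 (permutation test, adjusted p = 0.119). Relative to gene number in the main setting, I was at 1.17, III at 1.24, IV at 0.786 and V at 0.559 (permutation tests, adjusted p of 0.0414, 0.00435, 0.00435 and 0.0003). With the 515 strongest peaks I, III and IV lost that call (permutation tests, adjusted p of 0.619, 0.0530 and 0.0787). Summits on X were more often outside gene start windows, 134 of 210 (63.8%) against 385 of 820 (46.95%) on autosomes (odds ratio 1.99, Fisher's exact test, p = 1.4e-05, a comparison added after the data were examined). The call for II was lost relative to gene number (ratio 1.13, permutation test, adjusted p = 0.0629) and with the 515 strongest peaks (ratio 1.18, permutation test, adjusted p = 0.105). The length-based call for III was lost in 3 alternatives, at ratios from 1.11 to 1.21. With each chromosome cut into 3 equal parts, the middle part held 57.2% of peaks on II, 50.9% on I, 49.1% on III and 46.5% on V (exact binomial tests, adjusted p of 3.5e-11, 6.8e-06, 5.4e-05 and 0.00155), 39.1% on IV (exact binomial test, adjusted p = 0.168) and 26.7% on X (exact binomial test, adjusted p = 0.0486). The middle part held 36.0% of genes on II, 39.5% on I, 40.3% on III, 36.0% on V, 40.6% on IV and 35.7% on X, and against these shares the same chromosomes passed, with adjusted p from 5.9e-09 on II to 0.0273 on III and 0.0122 on X (exact binomial tests). Only II kept this latter call in all alternatives, and with the 515 strongest peaks I, III, V and X all lost it (exact binomial tests, adjusted p of 0.163, 0.826, 0.0722 and 0.163). The call for III against equal parts was lost without replicate 2 (41.4%, exact binomial test, adjusted p = 0.0515) and with the 515 strongest peaks (41.9%, exact binomial test, adjusted p = 0.163). That for X was lost in 4 alternatives, with shares from 28.2% to 31.4% and adjusted p in the exact binomial test from 0.135 to 0.652.

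**Figure D3:**
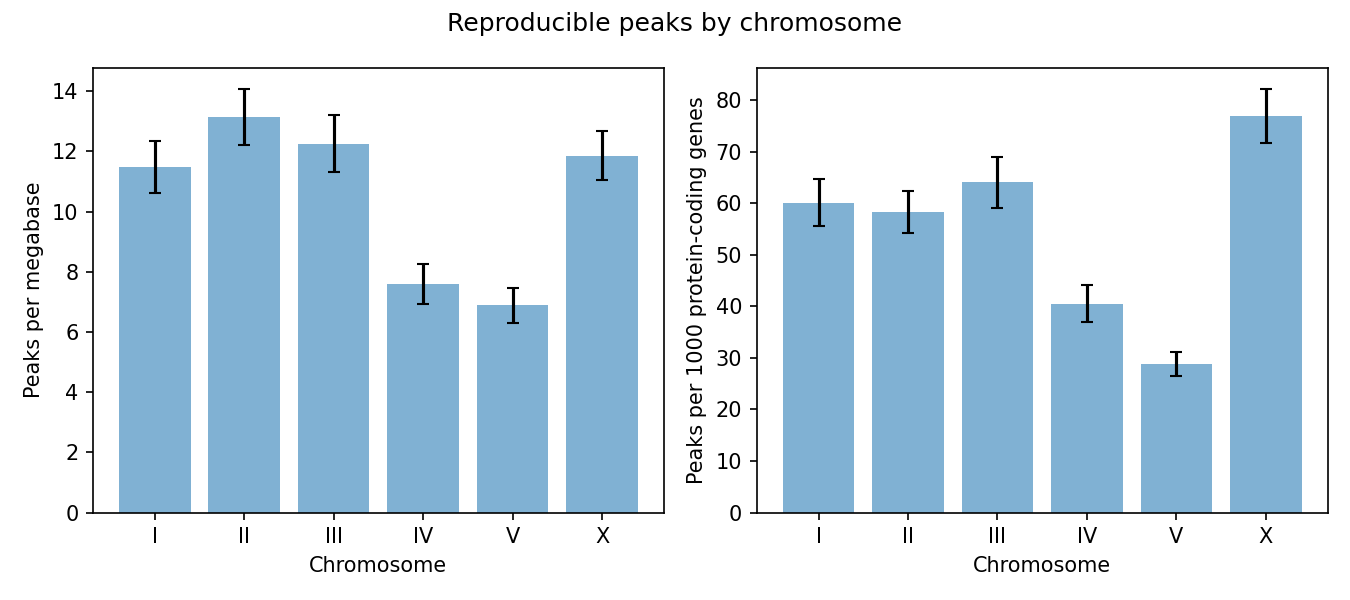
Reproducible peaks per megabase (left) and per 1000 protein-coding genes (right) for each chromosome; bars are values of the single pooled list and error bars are counting error, the square root of the count on the same scale. X had 76.9 peaks per 1000 genes and V had 28.8.

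Summits were rich in G and C and in a few short words. Windows around summits had 45.01% ± 8.36 G and C (SD over peaks), against 35.7% ± 8.74 in the flanks. GAGAGA was present at 28.6% of summits and 7.33% of flanks (ratio 3.91, exact McNemar test, adjusted p = 3.5e-39), and AGACGC at 13.4% and 1.80% (ratio 7.46, exact test, adjusted p = 7.3e-24). GCGCGC was present at 5.15% and 0.388% (ratio 13.3, exact test, adjusted p = 3.4e-13), or at a ratio of 7.07 to flanks 500 bases away (exact test, adjusted p = 3.2e-08), and CACGTG, the E-box, at 6.21% and 1.60% (ratio 3.88, exact test, adjusted p = 5.1e-09). Of the nuclear receptor half-sites, AGGTCA was at 2.62% of both summits and flanks (exact test, adjusted p = 0.892), AAGTCA was at 3.79% and 4.95% (exact test, adjusted p = 0.408), and AGTTCA was lower at summits, 3.59% against 7.72% (exact test, adjusted p = 1.2e-05). TGATAA, bound by GATA factors, TATAAA and TGTTTA were also lower, with ratios of 0.556, 0.427 and 0.605 (exact tests, adjusted p of 4.8e-05, 1.1e-07 and 0.00586), although TGTTTA lost its call in 2 alternatives, at ratios of 0.642 and 0.643. The words lower at summits were not compared at matched G and C content. TGACTCA and CTGTAG did not pass (exact tests, adjusted p of 0.369 and 0.296). With windows of 100 bases to each side both passed, in opposite directions. TGACTCA was higher at summits (ratio 1.75, exact test, adjusted p = 0.0360) and CTGTAG lower (ratio 0.7, exact test, adjusted p = 0.0445). Of all 2080 words, 610 passed the threshold, 360 higher and 250 lower at summits, and ACGCAG was 9.05 times as frequent at summits as in flanks.

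**Figure D4:**
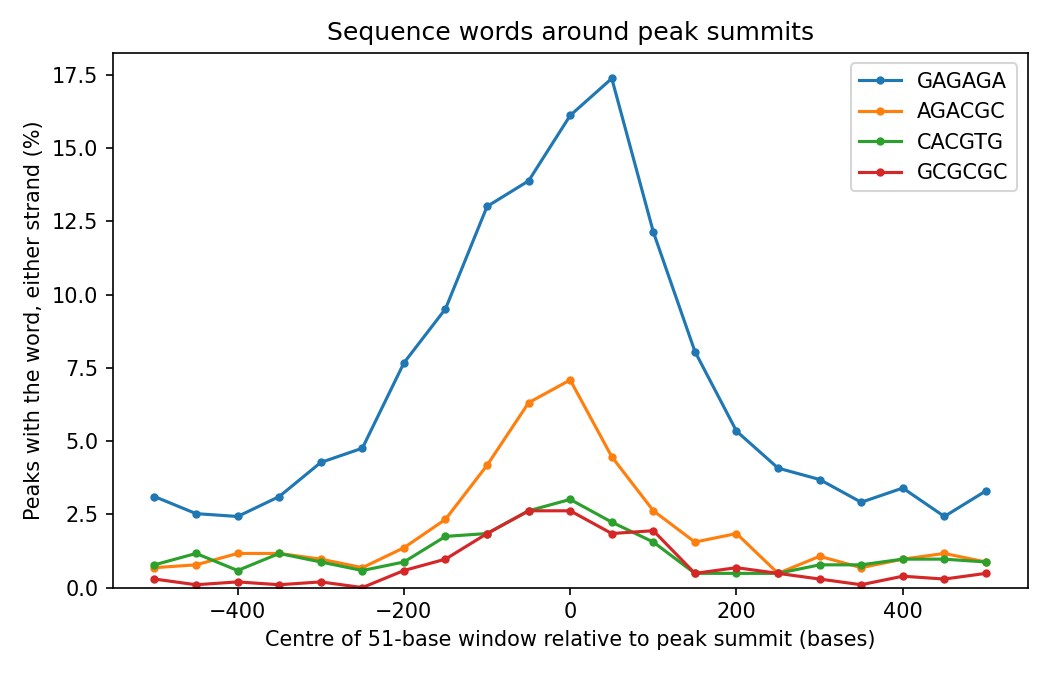
Share of the 1030 reproducible peaks with each word on either strand (y axis, percent), by distance of the window centre from the summit (x axis, bases). Each line is 1 word. These windows were narrower than the 50 bases to each side counted in the text, so the shares at the summit are lower here. AGACGC and CACGTG were most frequent in the window at the summit, GCGCGC was at 2.62% there and at -50 bases and at 1.84% at 50 bases, and GAGAGA was at 16.1% there, 13.9% at -50 bases and highest at 50 bases (17.4%).

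Peaks also lay near small noncoding RNA genes. A summit was within 250 bases of a tRNA gene for 27 peaks against 3.55 expected (ratio 7.61), of a snoRNA gene for 17 against 2.27 (ratio 7.49), and of a snRNA gene for 10 against 0.721 (ratio 13.9), each with adjusted p = 0.000167 in the permutation test. The tRNA ratio was 4.67 within 500 bases, 4.29 with the 515 strongest peaks and 4.83 with peaks among the strongest of both replicates, and the snRNA ratio was 8.04 within 500 bases (permutation tests, adjusted p from 0.000167 to 0.0025). Many tRNA and snRNA genes have near copies, and of these peaks only 2 near tRNA genes and 2 near snRNA genes were of unique sequence, so reads shared between copies are not excluded there. Against placements in unique sequence the tRNA ratio was 1.15, with 2 peaks against 1.74 expected (permutation test, adjusted p = 1). The tRNA enrichment was therefore not seen in unique sequence. The snRNA ratio there was 5.45, with 2 peaks against 0.367 expected (permutation test, adjusted p = 0.287), too few to decide. In the same setting snoRNA genes were near 16 peaks (ratio 7.01, permutation test, adjusted p = 0.0005). MicroRNA genes were near 3 peaks (permutation test, adjusted p = 0.468) and rRNA genes near 0 (permutation test, adjusted p = 1).

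The tagged gene itself had few listed regions. Within 20000 bases of nhr-11 (WBGene00003610, IV 9070003 to 9073622, plus strand), replicate 1 listed 1 region and replicate 2 listed 2 regions, at the 0.415 and 0.780 percentiles of windows of the same length. The nearest reproducible summit was 91841 bases from the gene start. The gene unc-119 (WBGene00006843, III 10902641 to 10908935) is mutated in this strain, and the transgene carries a rescuing copy. There 1 reproducible peak had its summit at 10903511, 870 bases downstream of the start, with rank 859 and a signal of 59.5. That region ranked 1298 in replicate 1 and 803 in replicate 2, and listed regions around unc-119 were at the 80.5 and 31.9 percentiles. Reads from the rescuing copy may map here, so binding at this peak cannot be told apart from them.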

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

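The restrictions to peaks among the strongest of both replicates and to unique sequence were chosen after seeing the data. The share of peaks at gene starts stayed above random placement in all 8 alternatives, from 37.4% to 68.5%. The highest share, with the wide windows, had the lowest ratio to random placement (1.21, with 56.8% expected), and the narrow windows had the highest (3.37, with 11.1% expected); midpoints in place of summits test nothing, since 1026 summits lie within 1 base of the midpoint. Replicate overlap ran from 51.8% to 66% in its 5 alternatives. The upper part of the list by signal held 515 peaks. Genes bound numbered 1042 with windows of 2000 bases to each side, 361 with the 515 strongest peaks and 427 with peaks among the strongest of both replicates, as these settings widen the windows or use fewer peaks. The wide windows called 7 lists as bound more often in place of 4. The ratio of X to its length was 1.11 to 1.16 with 1 replicate left out and 1.03 in unique sequence, with placements limited to such sequence. There 1 noncoding class in place of 3 was called, and 3 lists in place of 4 were bound more often. The tRNA ratio there was 1.15 in place of 7.61, and the snRNA ratio was 5.45 in place of 13.9, on 2 peaks. Around nhr-11 the pooled percentile was 0.930, 0.569 within 10000 bases and 8.83 within 40000 bases; the cause was not tested.

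Odds ratios of lists that did not pass the main test crossed 1 as follows; the cause was not tested. With the narrow window they were 1.04 for neuronal, 0.923 for germline and 1.27 for proteasome genes. With the wide window they were 2.02 for neuronal, 0.845 for germline, 2.11 for lipid metabolism, 1.52 for insulin-like and 1.17 for proteasome genes. With the nearest gene only they were 1.03 for lipid metabolism, 1.02 for insulin-like and 1.21 for proteasome genes. With the 515 strongest peaks they were 1.39 for neuronal, 1.45 for lipid metabolism, 1.43 for insulin-like and 1.70 for proteasome genes, and the ratio of AGGTCA was 1.13. With peaks among the strongest of both replicates they were 1.17 for neuronal, 1.22 for lipid metabolism, 1.21 for insulin-like and 1.43 for proteasome genes. With 1 replicate left out they were 0.799 to 1.66 for neuronal and 0.826 to 1.13 for lipid metabolism genes, and AGGTCA was at 0.906 to 1.09. Read depth, which would limit the weaker peaks, is unknown.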

Other observations

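The tests of control reads around nhr-11 and of gene spacing on X were chosen only after the result was seen. GAGAGA was at 35.1% of the 385 autosomal summits away from gene starts against 6.36% in flanks, and at 26.2% of the 511 summits at gene starts against 7.83% (exact McNemar tests, adjusted p of 1.3e-25 and 6.5e-14). It did not pass at the 134 summits on X away from gene starts, 19.4% against 8.21% (exact test, adjusted p = 0.128), or at the 41 peaks of ribosomal protein genes, 7.32% against 8.54% (exact test, adjusted p = 1). Differences between these kinds of peaks were not tested.

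Peaks on X away from gene starts included 7 of the 20 strongest peaks. The median share of their 31-base words found once in the genome was 100%, as it also was in random regions. Repeated sequence was thus argued against for most of these peaks. A median cannot exclude it for a part of them. Wider gene spacing on X cannot be told apart from another cause: enrichment at gene starts on X was 0.846 times that on autosomes as a ratio of shares (95% interval 0.687 to 1.01) and 0.667 times as a ratio of odds (95% interval 0.482 to 0.904), so only the latter lies below 1. A candidate explanation is the sequence at which the dosage compensation complex is recruited to X: its 12-base consensus TCGCGCAGGGAG, with at most 2 mismatches within 100 bases of the summit, was found at 15 of these 134 peaks (11.2%, interval 6.90 to 17.6) against 3 of 385 on autosomes (0.779%; Fisher's exact test, p = 3.2e-07) and 0.1% of 2000 random X positions, and at 3 of the 7 strongest. The explanation covers only the peaks with the consensus, and whether other tagged proteins give signal at these sites was not analysed here.

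Extra transgene copies of nhr-11 were expected to add listed regions there. The percentile of 0.780 in the higher replicate argued against added regions. It cannot decide on reads of the extra copies, since a control with the same copies would offset them. Instead, the gene lay in an interval without listed regions, IV 9039851 to 9089867 in replicate 1 (50017 bases) and 9042273 to 9090863 in replicate 2 (48591 bases), longer than at least 99.97% of such intervals (99.9716 percentile in replicate 2). A candidate explanation is that the control library carried reads of the extra copies, but the control was not analysed here and intervals of nearly this length with mostly unique sequence occur elsewhere, such as 45492 bases on II in the pooled list with 84.2% unique words. Repeated sequence cannot be told apart from this, since 77.3% of the words in the interval were found once, between the bounds set for either answer. No biological explanation was tested.

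For GCGCGC, the fixed word with the highest ratio, G and C content alone was argued against as the whole cause. Position at a gene start alone was argued against in the same way. The comparisons matched either the distance from a gene start or the G and C content, not both. They therefore cannot decide on the base composition of gene starts with equal G and C content. Words lower at summits were not matched. GCGCGC was 9.77 times as frequent at summits of gene start peaks as at the same offsets from unbound genes. Against random positions with the same number of G and C bases it was 2.96 times as frequent, lower than the ratio of 13.3 to the flanks, which was 7.07 with flanks 500 bases away. For AGACGC the ratio was 3.56 in place of 7.46, for CACGTG 2.18 in place of 3.88, and for GAGAGA 3.83 in place of 3.91. These ratios carry no test. Part of the enrichment of GCGCGC, AGACGC and CACGTG may therefore follow G and C content, while that of GAGAGA changed little. No biological explanation was tested.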
